A study of Mus musculus with 4 samples.

How the data were processed

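Liver cells of male and female C57BL/6J mice, an inbred laboratory strain, were profiled by single-cell RNA sequencing on the 10x Chromium droplet platform, which tags each captured transcript with a cell barcode and a unique molecular identifier (UMI). Per the labels, mice of 12 weeks had received 400 mg/kg acetaminophen (APAP), an analgesic that injures the liver at high dose, or phosphate-buffered saline (PBS) into the peritoneum, and cells were collected after 48 h. The liver was dissociated in place by perfusion with a digestion medium, and the cells were not sorted. There was 1 library for each sex and treatment, 4 in all. Isolation was spread over 2 days and sequencing was done together. Which library belongs to which day, and how many mice each library holds, is not given in the sources used here.

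The deposited values are whole-number UMI counts per gene and barcode, 1 matrix per library, which the authors had limited to barcodes called as cells and had not normalised. Cell Ranger, Seurat and the genome build GRCm38 are named per the submitters' processing notes, with no version, role or order. Each matrix held 31053 genes, and 31011 of their identifiers (99.86%) were found in the GENCODE M21 annotation of GRCm38, which supplied the coordinates. No cell annotation by the authors was used, so the class names below are rebuilt from markers and may differ from theirs.

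Barcodes with at least 500 UMIs, at least 200 genes and at most 50% of UMIs from mitochondrially encoded genes were kept, 8914 of 15285. The limit on mitochondrial UMIs alone left out 47.7% of barcodes of the male APAP library, 43.3% of the female APAP library, 39.7% of the male PBS library and 33.3% of the female PBS library. Scrublet, as built into scanpy, was run per library and marked 17 barcodes (0.19%). A caller that marks under 0.5% of barcodes has not worked, so doublets are best taken as not removed. The 17 marked barcodes were left out and 8897 cells remained. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen with the library as batch key, were scaled with a limit of 10 and reduced to 30 principal components. An exact graph of 15 neighbours was clustered with the Leiden method at resolution 1.0, without integration of the libraries, and gave 27 clusters.

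Clusters were named from markers of 17 cell classes written before the data were examined. The rule that turned markers into names was set after the clusters were seen. It asked for a mean scaled marker score of at least 0.5, at least 3 markers detected in at least 10% of the cluster's cells, and a runner-up class below 0.6 of the best score. Hepatocyte was never counted as the runner-up, so a hepatocyte score did not make a cluster ambiguous. A cluster also stayed unnamed where another class had more markers among its top 10 genes by fold. Clusters 0 and 5 stayed without a name, and their share of each library is given with the classes. Classes are written as X-like throughout.

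Raw UMIs were summed over the cells of a class in each library and expressed as counts per 1000000 UMIs of that sum (CPM). Ratios of CPM have exact conditional binomial 95% intervals, counts have exact Poisson intervals and shares have exact Clopper-Pearson intervals, all of which cover counting error only. Each group held 1 library, so no test was run and no p-value or standard error is given, and differences between animals, days and libraries are not measured. The 2 sexes were set side by side and not used as replicates of each other. A count of 0 was replaced by 3 counts per library and the ratio is then written as a bound. No ratio was formed where both counts were 3 or fewer or where that bound fell on the opposite side of 1. The last part of this rule was added after results were seen.

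The contrasts were APAP over PBS in each sex, female over male in each treatment, and the female minus the male log2 APAP ratio. Other classes were compared where each library held at least 50 cells of the class. Named genes followed a rule of size. In hepatocyte-like cells they had at least 50 CPM in the higher library and at least a 2-fold ratio in the same direction in both sexes, or in both treatments, and the first 10 higher and 10 lower by the smaller ratio were taken. For the difference of responses the first 5 in each direction were taken among genes of at least 50 CPM in a library. In other classes the first 5 in each direction were taken among genes with a higher CPM there than in hepatocyte-like cells of the same library. Mitochondrial, ribosomal, haemoglobin and unnamed genes were not named under this rule. Some genes that met the rule are not reported here.

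Further genes are named as members of 28 gene lists written before the data were examined. For each list the median log2 ratio of members with at least 10 CPM in a library was placed among 10000 random lists of the same size drawn from the same 20 expression bins. A list stands apart when its median lies below the 2.5th or above the 97.5th percentile, which describes these libraries and is not a test. Intervals of list medians come from 2000 bootstrap draws over members. Cell cycle shares were taken after thinning each cell to 500 UMIs. Genes of near-identical families (Mup, Cyp2b, Cyp2c, Cyp4a, Sult2a, Serpina1, Saa, Gsta, Gstm, H2) can share reads, so the split of counts among such members is uncertain.

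The calculation was tested on simulated counts drawn from the real hepatocyte-like sums, with 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn as an independent Poisson count, the model that the intervals assume, with no spread between cells. The simulation therefore checks the arithmetic. It cannot show how the intervals or list percentiles hold where few cells carry most UMIs. Of the 100 genes changed 2-fold, 99 had the right direction for APAP over PBS in males (6270 genes), 100 for APAP over PBS in females (6128 genes), 100 for female over male in PBS (6167 genes) and 99 for female over male in APAP (6361 genes). All 100 genes changed 4-fold had the right direction in each of these contrasts. In the same order, the interval held the true ratio for 97, 95, 92 and 97 of the 100 genes changed 2-fold, and for 92, 95, 96 and 94 of those changed 4-fold. Among 100 random lists of 15 unchanged genes, 3, 5, 4 and 3 stood apart, and all 20 raised lists did.

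Alternatives covered the barcode filter, doublets, clustering resolution, clustering of each library on its own, edgeR's TMM factors, DESeq2's size factors, totals without mitochondrial and the 20 most abundant genes, means per cell, thinning, and filters on low counts. Another 8 were chosen after the data were seen: cells of at least 3000 UMIs, cells of under 3000 UMIs, leaving out a stress-led cluster, leaving out a shallow Kupffer-like cluster, counting cluster 5 as Kupffer-like, removing 198 barcodes with the highest doublet scores, and leaving out the 1 or the 3 cells with the most UMIs of a gene or list in each library. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.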

Results

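RNA was counted in single liver cells of 4 libraries, 1 each from male mice given PBS, male mice given APAP, female mice given PBS and female mice given APAP. The male PBS library held 5549 barcodes and 13971949 UMIs, the male APAP library 1926 and 7457690, the female PBS library 5457 and 20117950, and the female APAP library 2353 and 10084870. After filtering, 3306 cells of the male PBS library remained (median 1230 UMIs per cell), 944 of the male APAP library (1109.5), 3356 of the female PBS library (2184) and 1291 of the female APAP library (1496). Xist, the RNA that coats the inactive X chromosome, had 0 UMIs in both male libraries, 9676 UMIs (95% Poisson interval 9484 to 9871) in the female PBS library and 2850 (2746 to 2957) in the female APAP library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 2104 UMIs in the male PBS library, 666 in the male APAP library, 2 in the female PBS library and 0 in the female APAP library, so the sex labels matched the counts.

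The first question was which cell classes made up each library. Kupffer-like cells, the resident macrophages of the liver sinusoids, were a smaller part of both APAP libraries. They made up 21.5% of cells (95% binomial interval 20.1% to 22.9%) in the male PBS library and 7.63% (6.02% to 9.51%) in the male APAP library, and 16.7% (15.5% to 18.0%) and 11.4% (9.70% to 13.2%) in the female libraries. Cells like monocytes or monocyte-derived macrophages, which enter injured liver from the blood, were a larger part. They were 0.968% (0.663% to 1.36%) and 6.57% (5.07% to 8.34%) in the male PBS and APAP libraries, a ratio of 6.79 (4.46 to 10.3), and 1.31% and 2.87% in the female libraries, a ratio of 2.19 (1.42 to 3.37). T-cell-like shares were 6.50% and 3.49% in the female PBS and APAP libraries, a ratio of 0.537 (0.392 to 0.735), and B-cell-like shares 3.10% and 1.70%, a ratio of 0.550 (0.349 to 0.867). In males they were 1.75% and 1.27% for T-like cells, a ratio of 0.725 (0.391 to 1.34), and 1.63% and 0.953% for B-like cells, a ratio of 0.584 (0.289 to 1.18). Both male intervals include 1, with 12 and 9 cells after APAP. Plasmacytoid dendritic-like cells numbered 22 and 1 in the male PBS and APAP libraries and 19 and 2 in the female ones. Cells like NK cells or ILC1 numbered 22, 6, 53 and 13, erythroid-like cells 9, 4, 55 and 1, and cholangiocyte-like cells 2, 0, 6 and 0, in the male PBS, male APAP, female PBS and female APAP libraries. The 0 cholangiocyte-like cells allow shares of up to 0.318% and 0.232%.

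Hepatocyte-like cells made up 46.1%, 49.2%, 46.5% and 51.4% of the same libraries in that order, an APAP over PBS ratio of 1.07 (0.990 to 1.15) in males and 1.10 (1.04 to 1.18) in females. Endothelial-like cells were a smaller part of the male APAP than of the male PBS library, with a ratio of 0.684 (0.578 to 0.810), and a larger part of the female one, with a ratio of 1.25 (1.10 to 1.42). Neutrophil-like cells had ratios of 2.07 (1.05 to 4.09) in males and 1.04 in females, and stellate- or fibroblast-like cells 0.834 (0.564 to 1.23) in males and 1.38 (1.01 to 1.89) in females. Clusters 5 and 0 stayed without a name. Cluster 5, led by the proliferation genes Pclaf, Top2a, Mki67 and Birc5, held 8.05% of cells in male APAP, 0.877% in male PBS, 1.55% in female PBS and 1.78% in female APAP. Cluster 0, led by contractile genes such as Acta2, Tagln, Mylk and Des, held 59 cells of the male APAP library (6.25%), 1 of the male PBS library, 5 of the female APAP library (0.387%) and 0 of the female PBS library, which allows up to 0.0890%. A cluster taken mostly from 1 library can reflect that library and not a cell type.

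Shares depended on clustering and on the barcode filter. In neither sex could a monocyte-like ratio be formed without a barcode filter or with each library clustered on its own. The T-like ratio could not be formed at resolution 0.5. In these cases the class was absent or had no cells in a library compared, so stability there is not known. The male Kupffer-like ratio of 0.355 (0.282 to 0.448) became 0.126 without cluster 9, a cluster of median 873 UMIs that held 54 of the 72 male APAP cells of the class, 0.200 without the barcodes of highest doublet scores, 0.502 without a barcode filter, 0.708 at resolution 2.0 and 0.734 with each library clustered on its own. Cluster 5, whose best marker score was that of Kupffer cells, would bring the Kupffer-like shares to 22.4% and 15.7% in male PBS and APAP, a ratio of 0.701 (0.597 to 0.824), and to 18.3% and 13.2% in females, a ratio of 0.721 (0.616 to 0.844). The hepatocyte-like ratios were 0.646 and 0.790 without a barcode filter, the female endothelial-like ratio was 0.501 with each library clustered on its own, and the female stellate-like ratio was 0.336 under the stricter filter and 0.791 at resolution 0.5. The male stellate-like ratio lay above 1 under 5 alternatives. It was 3.75 (2.74 to 5.12) at resolution 0.5, 2.42 at resolution 2.0, 2.54 without the barcodes of highest doublet scores, 1.90 under the stricter filter and 1.76 without a filter. Its direction is therefore not settled. The unnamed cluster 0, with 59 male APAP cells and 1 male PBS cell, had its best marker score, 0.434, for stellate cells or fibroblasts. The stellate-like class held 30 male APAP cells, against 87 at resolution 2.0 and 89 without the barcodes of highest doublet scores. Whether cells of cluster 0 entered the class there was not examined.

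**Figure D1:**
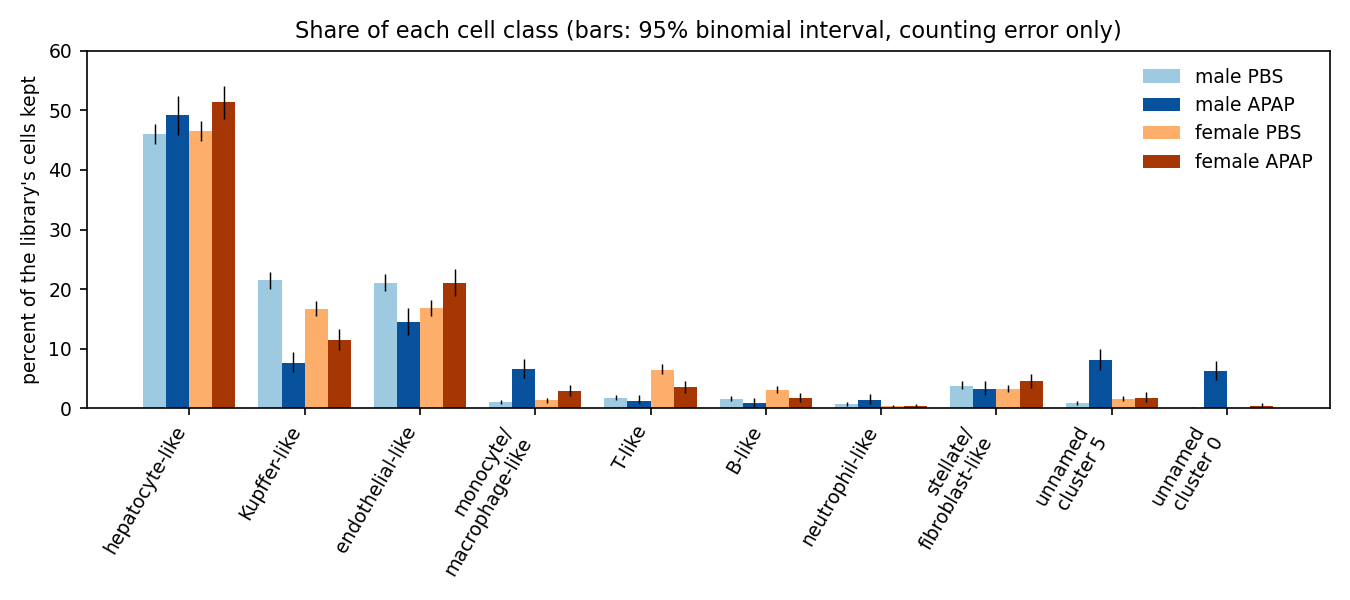
Share of the filtered cells of each library (y axis, percent) in each cell class and in the unnamed clusters 5 and 0 (x axis), with 1 bar per library and 95% binomial intervals that cover counting error only. Kupffer-like bars are lower in both APAP libraries, at 7.63% and 11.4%, and monocyte-like bars are higher, at 6.57% and 2.87%.

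The main comparison asked how hepatocyte-like cells after APAP differed from those after PBS in each sex. Saa3, a serum amyloid A gene, had 518 UMIs after PBS and 1 after APAP in males (log2 ratio −6.71, 95% interval −12.01 to −4.22) and 544 and 6 in females (−4.62, −6.07 to −3.49). Glul, the glutamine synthetase of hepatocytes next to the central vein (ENSMUSG00000026473, GRCm38 chromosome 1, 153899944 to 153909723), was 92.2-fold lower in males, at 677 CPM after PBS and 7.34 CPM after APAP (−6.53, −7.84 to −5.48), and 5.36-fold lower in females, at 637 and 119 CPM (−2.42, −2.59 to −2.26). Slc1a2, a glutamate transporter gene, was at least 23.4-fold lower in males, with 0 UMIs after APAP, and 34.5-fold lower in females. Few PBS cells carried these genes. Slc1a2 UMIs lay in 40 of 1523 male PBS cells, with 42.4% in 3 cells, and in 108 of 1561 female PBS cells. Glul UMIs lay in 364 male PBS cells, with 26.8% in 3 cells, and in 341 female PBS cells, with 14.3% in 3. Scd1, stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), was 18.8-fold lower in males (−4.23, −4.50 to −3.98) and 3.66-fold lower in females (−1.87, −1.94 to −1.80).

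Other genes at least 2-fold lower after APAP in both sexes were Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis (3.11-fold in males and 4.76-fold in females), Dio1, a thyroid hormone deiodinase (3.63-fold and 3.85-fold), Gulo, which makes the last step of vitamin C synthesis (3.13-fold and 2.74-fold), Gpcpd1 (3.36-fold and 5.23-fold) and Ces3b (3.81-fold and 2.83-fold). Genes at least 2-fold higher in both sexes were led by Gsta1, a glutathione S-transferase (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684), at 13.9 and 183 CPM in males (13.1-fold; 3.71, 3.29 to 4.14) and 2.84 and 99.9 CPM in females (35.2-fold; 5.14, 4.57 to 5.75). Alas1, the first enzyme of heme synthesis, was 3.19-fold higher in males and 3.61-fold in females. Id3, an inhibitor of helix-loop-helix transcription factors, was 3.23-fold and 5.05-fold higher, and the apolipoprotein gene Apoa4 3.04-fold and 6.10-fold. AY036118 (5.73-fold and 4.12-fold), Cstb (3.09-fold and 2.12-fold), Dynll1 (2.30-fold and 2.21-fold), Echdc3 (2.16-fold and 2.54-fold) and Fabp2 (2.07-fold and 2.34-fold) followed. Without the 1 cell with the most UMIs of the gene in each library, the log2 ratio was 0.85 for Apoa4 in males, −5.48 for Saa3 in females, −6.03 for Slc1a2 in females and −2.52 for Ces3b in males. Saa3 in males was left with 0 UMIs after APAP and a bound of −5.03. Hepatocyte-like cells came from clusters that differed between libraries. Cluster 24 held 376 male PBS cells and 0 male APAP cells, cluster 3 held 82 male APAP cells of its 88, and cluster 25 held 74 female PBS cells of its 75. Cluster 3 was led by Gsta1, Mup17 and Cyp2a5, with Mup11, Igfbp1, Mup7, Ddit3 and Atf3 also among its top 10 genes. It is called stress-led for Gsta1, Igfbp1, Ddit3 and Atf3. Its hepatocyte score of 0.54 was just over the limit of 0.5. Glul was among the leading genes of cluster 24, and Oat, Glul, Slc1a2, Lect2 and Gulo were among those of cluster 25. Ratios of class sums for these genes do not separate fewer such cells from lower expression within cells.

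Zonal genes differed by zone in males, while in females the intervals over members of the pericentral and periportal medians overlapped. Of the 16 measured pericentral genes, expressed near the central vein where APAP is oxidised to its toxic product, 11 were at least 2-fold lower after APAP in males and 1 was higher, with a median log2 ratio of −1.55 (95% interval over members −2.93 to −0.78). In females 5 were at least 2-fold lower and 0 higher, with a median of −0.75 (−1.27 to −0.43). Both medians lay below all 10000 random lists. Oat, ornithine aminotransferase, had log2 ratios of −4.46 in males and −1.36 in females, Cyp27a1 −1.85 and −1.27, and Cyp2e1, the main enzyme that oxidises APAP, −1.20 and −0.77. Cyp2a5 (2.00 and −0.86) was the male exception. Of the 16 periportal genes, which serve urea synthesis and gluconeogenesis near the portal vein, 2 were at least 2-fold lower in each sex and 0 higher, with medians of 0.00 in males (percentile 34.4) and −0.23 in females (percentile 0.820; 0.19 in cells of under 3000 UMIs). Cyp2f2 had −1.63 and −1.18, Cps1 0.09 and −0.20, and Arg1 0.75 and 0.43.

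**Figure D2:**
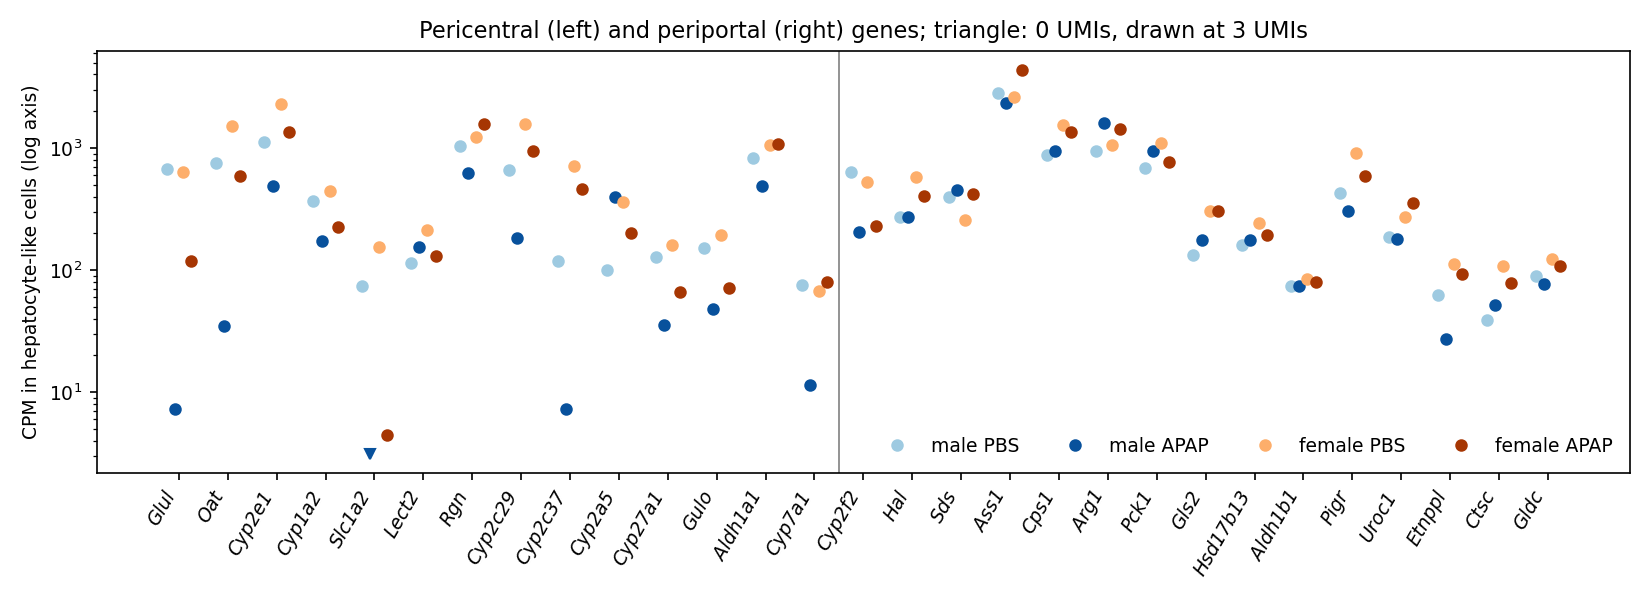
CPM (y axis, log scale) of pericentral genes (left) and periportal genes (right) with at least 50 CPM in a library, summed over hepatocyte-like cells, with 1 point per library and triangles for 0 UMIs drawn at 3 UMIs. Glul lies at 677 CPM in the male PBS and 7.34 CPM in the male APAP library, while the log2 ratios of Cps1 after APAP were 0.09 in males and −0.20 in females.

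Lists of hepatocyte metabolism mostly had medians below 0 after APAP. Of 15 bile acid synthesis and transport genes, 11 were at least 2-fold lower in males (median −1.12, percentile 0) and 7 in females (−0.95, percentile 0), with 0 higher in either. Cyp7b1 had log2 ratios of −3.18 and −2.26, the bile acid importer Slc10a1 −1.09 and −0.95, and Nr0b2, a bile acid-responsive repressor, −1.21 and −1.61. Of 16 lipogenesis and sterol synthesis genes, 3 were at least 2-fold lower in males (−0.52, percentile 0.0100) and 4 in females (−0.66, percentile 0), among them Fasn at −1.47 in males. Of 8 genes of APAP bioactivation, conjugation and export, 3 were at least 2-fold lower in males (−0.71, percentile 0.0500) and 1 was higher in females (−0.33, percentile 1.85), with Cyp3a11 at −3.14 and −0.42. Plasma proteins and hepatocyte regulators had medians of 0.08 in males (percentile 52.6) and −0.51 in females (percentile 0), with Alb at 0.12 and −0.41 and Apoa1 at 0.99 and −0.52. Fatty acid oxidation and PPARalpha targets (−0.09 and 0.04; 1 of 17 higher and 1 lower in males, 1 lower in females) and mitochondrially encoded genes (−0.10, percentile 14.3, and −0.23, percentile 1.92; 0 of 13 at 2-fold) lay closer to 0. Growth hormone axis genes had medians of 0.11 (percentile 63.2) and −0.36 (percentile 0.140), each with 2 of 14 members at least 2-fold higher. Members were also lower. Bcl6 was at least 2-fold lower in both sexes, and Igfbp1 was at least 2-fold higher in males and at least 2-fold lower in females. The median of the APAP metabolism list in males was 0.08 with cells thinned to 500 UMIs and 0.02 in cells of under 3000 UMIs. In females it was −0.20 (percentile 4.64) in cells of at least 3000 UMIs and −1.26 (percentile 0) in cells of under 3000 UMIs. In those shallower cells the female median was thus the lower one, and the bile acid medians were −0.47 in males and −1.50 in females.

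Stress and inflammation lists came next. Of 14 immediate early and dissociation genes, which respond within minutes to stimuli and to tissue digestion, 11 were at least 2-fold higher after APAP in males and 0 lower (median 1.62, interval over members 1.34 to 3.33, percentile 100). In females 2 were higher and 2 lower (−0.33, percentile 0.180; 0.16 in cells of under 3000 UMIs). Fos had log2 ratios of 2.61 and −0.87, Junb 1.52 and −0.76. Of 10 integrated stress and ER stress genes, 5 were at least 2-fold higher in males (0.97, percentile 100) and 2 in females (−0.08, percentile 10.2), with Atf3 at 7.77 in males (1 and 44 UMIs) and Ddit3 at 3.04 and 1.37. Interferon-stimulated genes had medians of 0.63 (percentile 99.05) and 0.74 (percentile 99.95), with 2 and 4 of 9 members at least 2-fold higher and 0 lower, among them Isg15 at 0.63 and 1.41. The male interferon median was 0.13 (percentile 73.7) without the stress-led cluster 3 and 0.36 (percentile 83.6) in cells of under 3000 UMIs, inside the range of random lists. Of 21 acute phase genes, 5 and 4 were at least 2-fold lower and 1 and 0 higher (median −0.33, percentile 0.130, and −0.42, percentile 0), as for Saa1 at −3.00 and −1.02 and the haem scavenger gene Hpx at −1.05 and −1.83, while Hamp, which encodes the iron hormone hepcidin, had 2.42 and 0.29. In cells of under 3000 UMIs the acute phase medians were 0.07 in males and −1.03 in females (percentile 0, 11 of 21 lower), and the male one was 0.03 as a mean per cell. In the same cells the male medians were 2.49 for immediate early and 1.82 for integrated stress genes.

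Nrf2 targets, the antioxidant genes, had medians close to 0, 0.03 in males (4 of 22 at least 2-fold higher, 3 lower) and 0.02 in females (3 of 21 higher, 1 lower), with Nqo1 at 2.01 and −0.53, Hmox1 at 2.85 and 0.15 and Me1 at −2.07 and −0.61. The male Nrf2 median was −0.45 (percentile 0) without cluster 3 and −0.22 (percentile 1.95) in cells of at least 3000 UMIs. Medians of 9 p53 targets were 0.09 and −0.02, with 1 member at least 2-fold higher in each sex, and with Cdkn1a at 0.91 and 1.17. Ductal and fetal liver genes had medians of 0.40 (percentile 89.9) and 0.42 (percentile 78.8), repair macrophage genes 0.70 (percentile 99.9) and 0.20 (percentile 45.0), and the 3 measured stellate activation genes −0.22 and 0.18. In males the repair macrophage median was 0.22 (percentile 79.9) without cluster 3, 0.17 (percentile 74.8) in cells of at least 3000 UMIs and 2.16 (percentile 100) in cells of under 3000 UMIs. The male ductal and fetal median was −0.46 (percentile 6.66) without cluster 3 and 1.70 (percentile 99.98) in cells of under 3000 UMIs. In those shallower cells the stellate activation medians were 1.41 and 2.38. Genes of other cell types also differed. Sinusoidal endothelial genes had medians of −1.08 (percentile 0) in males and 0.57 (percentile 97.8; 0.08 in cells of at least 3000 UMIs and −0.31 under the stricter filter) in females, and erythroid genes 2.65 (percentile 100) and −2.45 (percentile 0). In the female PBS library 1 hepatocyte-like cell held 61.6% of the erythroid UMIs. The medians of the Nrf2 list in both sexes, of the p53, growth hormone and plasma protein lists in males, and of the fatty acid oxidation and repair macrophage lists in females took the other sign under at least 1 of the scalings tried. Across 2688 genes of at least 50 CPM in a library, the male and female log2 ratios had a Pearson r of 0.482 and a Spearman rho of 0.466, across genes, which are not independent replicates.

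**Figure D3:**
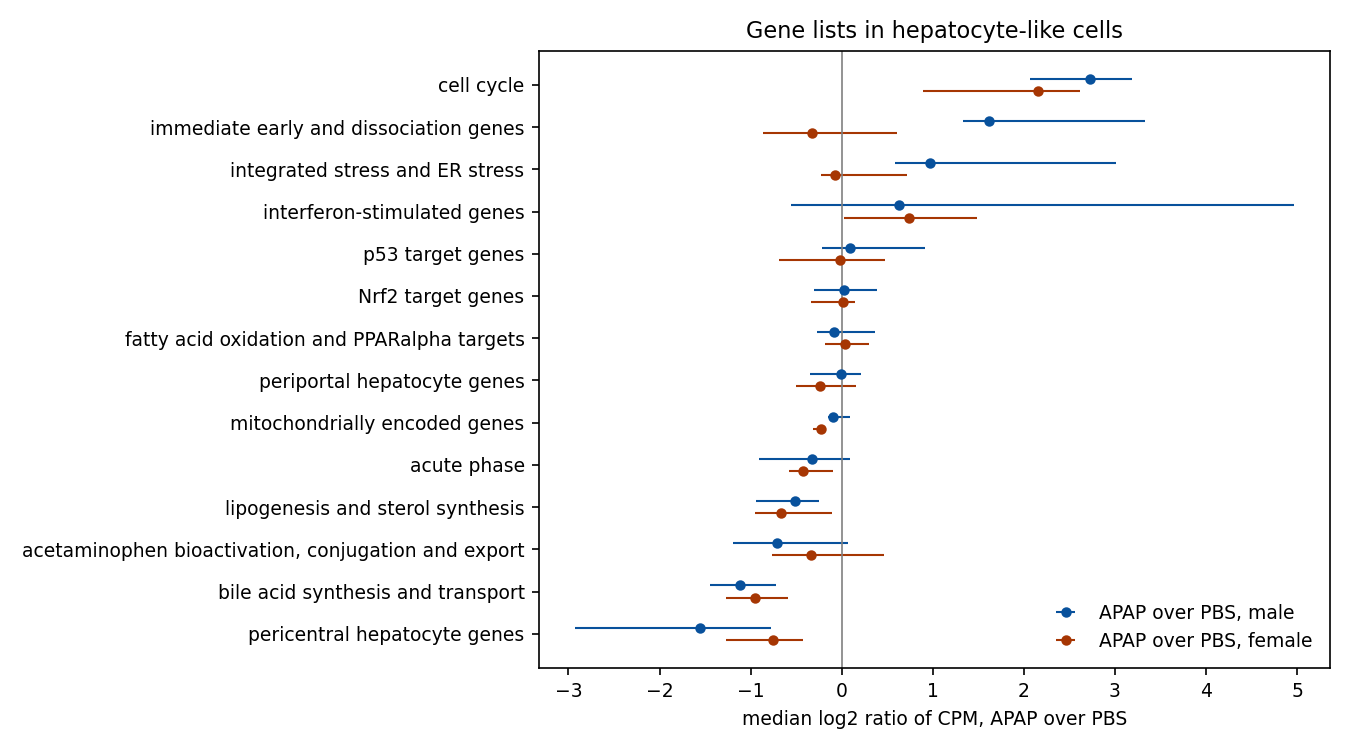
Median log2 ratio of APAP over PBS (x axis) for 14 gene lists (y axis) in hepatocyte-like cells, males in blue and females in red, with 95% bootstrap intervals over list members. Pericentral genes lie at −1.55 and −0.75, and immediate early genes at 1.62 and −0.33.

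Cell cycle genes of hepatocyte-like cells lay above the random lists after APAP. In males 24 of 27 members were at least 2-fold higher and 0 lower (median 2.73, interval over members 2.07 to 3.19, percentile 100), with the kinase gene Cdk1 at 4.34 (12 and 49 UMIs), and Top2a, a topoisomerase of dividing cells, at 4.46 (7 and 31 UMIs). In females 15 of 24 were at least 2-fold higher (2.16, 0.89 to 2.62, percentile 100). After thinning to 500 UMIs, 22 of 464 hepatocyte-like cells of the male APAP library held UMIs of at least 2 cell cycle genes (4.74%, 3.00% to 7.09%), against 12 of 1523 in male PBS (0.788%, 0.408% to 1.37%), 4 of 1561 in female PBS (0.256%, 0.0700% to 0.655%) and 2 of 663 in female APAP (0.302%, 0.0370% to 1.09%). Unthinned shares were 13.4%, 7.03%, 10.8% and 8.45% in the same order. By the same count after thinning, other classes of the male APAP library had 6 of 72 Kupffer-like cells (8.33%, 3.12% to 17.3%; 1.13% in male PBS), 2 of 30 stellate-like cells (6.67%), 3 of 62 monocyte-like cells (4.84%) and 1 of 136 endothelial-like cells (0.735%, 0.0190% to 4.03%; 1.01% in male PBS). Few cells carried these UMIs. In the male APAP library 3 cells held 51.7% of the 750 cell cycle UMIs. The male median was 1.82 without the 3 leading cells of each library and 4.34 among genes of at least 50 CPM. That filter goes by the library with the highest CPM, and the list summed to 787 CPM in male APAP against 172 CPM in male PBS. It favours members high in male APAP, so the value of 4.34 is no separate support. In the female APAP library 1 cell held 21.5% of 517 UMIs, and the female median was 0.63 without it, 0.82 with thinned cells, 0.46 (percentile 72.6, inside the random lists) in cells of under 3000 UMIs and −0.43 as a mean per cell.

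The next comparison asked how hepatocyte-like cells of females differed from those of males under each treatment. The sex-biased genes of mouse liver, most of them cytochromes P450, sulfotransferases and pheromone-binding proteins, separated the libraries under both. Sult2a2, a sulfotransferase of steroids and bile acids (ENSMUSG00000070811, chromosome 7, 13733505 to 13779636), had 3315 UMIs in female PBS and 0 in male PBS, at least 531-fold higher, and was at least 238-fold higher in APAP. Sult2a1 (at least 533-fold and 164-fold), Cyp2b9 (at least 423-fold in PBS; log2 7.48 in APAP, with 1 male UMI), Cyp2b13 (at least 506-fold and 55.8-fold), Cyp2c69 (87.8-fold, and at least 69.3-fold in APAP), the second hepcidin gene Hamp2 (59.0-fold and 75.3-fold), Acot3 and Slc22a26 (each with 1 male UMI in PBS, 8.45 and 8.50, and at least 29.5-fold and 26.4-fold in APAP) and Xist (at least 706-fold and 89.4-fold) were also higher in females.

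Major urinary protein genes, which encode secreted pheromone carriers, led those lower in females. Mup11 (ENSMUSG00000073834, chromosome 4, 60658466 to 60662411) was 467-fold lower in PBS and 399-fold lower in APAP, Mup7 532-fold and at least 367-fold, Mup20 64.1-fold and 34.3-fold, Mup21 66.7-fold and 33.0-fold, Mup1 43.0-fold and 61.7-fold, and Mup17 31.0-fold and 28.9-fold. The protease inhibitor gene Serpina1e was 195-fold and 101-fold lower, Selenbp2 170-fold and 61.0-fold, the organic anion transporter Slco1a1 25.2-fold and 35.0-fold, and the Y-linked helicase gene Ddx3y at least 228-fold and 67.3-fold. Without the 1 cell richest in the gene in each library, the APAP log2 ratio was −7.40 for Serpina1e and −6.49 for Slco1a1. Of 19 female-biased genes, 19 were at least 2-fold higher in females in PBS (median 6.46, interval over members 5.17 to 8.45) and 17 in APAP (4.72, 2.85 to 5.80), and 17 were so in both. Of the male-biased genes, 25 of 27 were at least 2-fold lower in PBS (−5.43, −6.10 to −4.64) and 23 of 25 in APAP (−4.07, −5.10 to −2.49), and the same 23 were lower in both. In cells of under 3000 UMIs the female-biased medians were 4.86 in PBS and 2.48 in APAP, and the male-biased ones −4.37 and −3.39.

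Further lists stood apart in both treatments. Pericentral genes had medians of 0.95 in PBS and 1.33 in APAP (7 and 10 of 16 at least 2-fold higher in females, 0 lower), with Cyp2c37 at 2.59 and 5.96. Bile acid genes had 0.82 and 0.96, APAP metabolism genes 0.83 and 0.95 with Cyp3a11 at 2.34 and 5.07, periportal genes 0.58 and 0.51 (in APAP 0.19, percentile 84.5, in cells of at least 3000 UMIs), and fatty acid oxidation genes 0.33 and 0.70. Lower in females were cell cycle genes (−2.32 and −3.29, with 21 of 27 members at least 2-fold lower in both) and ductal and fetal genes (−1.98 and −2.53, all 6 members lower in both, among them Krt8 at −2.00 and −1.51 and Spp1 at −7.31 and −4.73). The cell cycle median in PBS was −1.49 without the 3 cells richest in its UMIs in each library. In cells of under 3000 UMIs it was −0.67 in PBS (5 of 14 members lower and 4 higher, interval over members −1.23 to 0.80) and −1.75 in APAP. The ductal and fetal median in APAP was −1.63 without cluster 3 and −1.72 in cells of at least 3000 UMIs. In APAP, stress lists lay lower in females, at −1.34 for immediate early genes, −1.43 for integrated stress genes (−0.68 without the stress-led cluster 3) and −0.90 for p53 targets (−0.47 without that cluster). The p53 median was also lower in females in PBS, at −0.55 without the 1 cell richest in its UMIs in each library. In cells of under 3000 UMIs the APAP medians were −0.64 for APAP metabolism and −0.14 for bile acid genes. With cells thinned to 500 UMIs the APAP medians were −0.26 for APAP metabolism and −0.37 for bile acid genes, and the female-biased median was 2.13 in APAP and 4.22 in PBS. Across 2688 genes the log2 sex ratios in PBS and APAP had a Pearson r of 0.705 and a Spearman rho of 0.664, again across genes.

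The design also allowed the APAP response of females to be set against that of males. Igfbp1, an insulin-like growth factor binding protein gene (ENSMUSG00000020429, chromosome 11, 7197782 to 7202546), was 4.76-fold higher after APAP in males (log2 2.25, 2.03 to 2.47) and 9.47-fold lower in females (−3.24, −3.63 to −2.88), a female minus male difference of −5.50. In the male APAP library 1 cell held 36.6% of its 331 UMIs and 3 cells held 50.5%, which the interval does not cover. Igfbp1 was also among the leading genes of cluster 3, with 82 male APAP cells of its 88. Egr1, an immediate early transcription factor gene, had 1.52 in males and −2.63 in females. Cyp4a14, a fatty acid hydroxylase, had 5.27 (4 and 31 UMIs, 14 of the 31 in 1 cell) and −0.15, and the peroxisomal transporter gene Abcd2 had 4.31 and −0.43. The chemokine gene Cxcl10 had 6.70 and 1.23, with 40 of its 63 male APAP UMIs in 1 cell. In the other direction, Cyp4a12a had −2.62 and 4.20 (1.05 to 9.77, with 1 and 5 female UMIs), a difference of 6.83, and Glul differed by 4.11. Cyp2c37 (−4.01 and −0.63), Oat (−4.46 and −1.36) and the metal-binding protein gene Mt1 (−1.56 and 1.50) followed. By list, the female minus male difference was negative for immediate early genes (median difference −1.95, 11 of 14 members at least 2-fold lower, 0 higher), integrated stress genes (−1.17, and −0.30 without cluster 3), plasma proteins (−0.40) and erythroid genes (−5.12), all at or below percentile 0.0300. Of the erythroid UMIs in female PBS, 61.6% lay in 1 cell. The difference was positive for sinusoidal endothelial genes (1.37), male-biased genes (0.98, and −0.07 in cells of under 3000 UMIs), pericentral genes (0.69) and bile acid genes (0.46). Pericentral and bile acid medians were lower after APAP in both sexes, so a positive difference there is a smaller decrease in females. Sinusoidal endothelial and erythroid genes belong to other cell types, so their differences are not read as a response of hepatocytes. The pericentral difference was −0.15 with thinned cells and −0.06 under the stricter filter and that of bile acid genes −0.75 with thinned cells. The cell cycle difference of −0.43 (percentile 8.10) became −1.05 without the 1 leading cell of each library.

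Among other classes, Kupffer-like cells had at least 50 cells in each library, at 710 and 72 in males and 561 and 147 in females. The male APAP library held 27 such cells under the stricter filter and 37 without the highest doublet scores. Its Kupffer-like contrasts were therefore not recomputed under these alternatives. These cells leave out the unnamed cluster 5, led by proliferation genes, whose best marker score was that of Kupffer cells. Cluster 5 held 29 and 76 cells in the male PBS and APAP libraries and 52 and 23 in the female ones. The B-cell chemoattractant gene Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) was lower after APAP in both sexes, at 610 and 2 UMIs in males (−4.83, −7.88 to −2.97) and 6.96-fold in females, as were Gbp2b (5.64-fold and 2.71-fold), Runx1 (2.26-fold and 3.13-fold), Pou2f2 and Nrip1. Trem2, a lipid receptor of macrophages (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), was 3.29-fold higher in males (1.72, 1.27 to 2.15) and 2.34-fold in females (1.23, 0.77 to 1.68), with the ER folding genes Sdf2l1 (3.51-fold and 2.68-fold) and Pdia4 (2.37-fold and 2.32-fold) and with Ipo5 and Stip1. Of 8 MHC class II antigen presentation genes, 5 were at least 2-fold lower in males (median −1.31, percentile 0) and 0 in females (−0.54, percentile 0.0100), with Cd74 at −2.01 and −0.36. Of 16 cell cycle genes, 12 were at least 2-fold higher in males (1.75, percentile 100) and 10 in females (1.06, percentile 100). Inflammatory cytokines had medians of 0.84 (percentile 99.7) and 0.02 (percentile 61.1), with Ccl2 at 2.32 and 1.68 and Il1b at −3.32 and 0.61, interferon-stimulated genes −0.83 (percentile 0.0500) and −0.04 (percentile 32.1), and repair macrophage genes 0.18 (percentile 64.5) and 0.62 (percentile 100). The 3 measured neutrophil genes had −0.28 in males.

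In females against males, Kupffer-like cells had higher Cxcl13 (2.45-fold in PBS and 10.0-fold in APAP), Gbp2b (2.10-fold and 4.36-fold) and Cxcl9 (2.45-fold, and at least 12.4-fold in APAP, but −1.59 in log2 in PBS under the stricter filter), and lower Ranbp1 (2.08-fold and 2.15-fold) and Apex1 (2.01-fold and 5.73-fold). MHC class II medians were 0.48 in PBS and 1.24 in APAP. Most male APAP Kupffer-like cells lay in the shallow cluster 9 (54 of 72), while clusters 8 and 16 held most Kupffer-like cells of the other libraries, and Clec4f, a Kupffer cell marker, was at 1829 CPM in male APAP and 4730 CPM in male PBS. Albumin RNA, which these cells do not make, was at 1209, 1208, 3494 and 1420 CPM of Kupffer-like cells in the male PBS, male APAP, female PBS and female APAP libraries.

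Endothelial-like cells, which line the sinusoids, were compared next. The male APAP library held 44 such cells under the stricter filter, so its contrasts were not recomputed there. Rspo3, a Wnt enhancer (ENSMUSG00000019880, chromosome 10, 29452416 to 29535867), had 108 UMIs after PBS and 1 after APAP in males (−4.72, −10.03 to −2.21) and was 3.23-fold lower in females (−1.69, −2.46 to −0.98), and the cadherin gene Cdh13 was 3.14-fold and 2.11-fold lower. The list of central zone genes and Wnt ligands had medians of −1.45 in males (5 of 6 at least 2-fold lower) and −0.92 in females (3 of 6), both at percentile 0, with Wnt9b at −2.32 and −1.11 and Wnt2 at −1.15 and −0.11. Higher in both sexes were the ER chaperone genes Hspa5 (3.21-fold and 2.76-fold) and Manf (3.47-fold and 2.56-fold), the integrin gene Itgb3 (4.11-fold and 2.28-fold), Snrpg and Tmsb10. Endothelial activation and angiogenesis genes had medians of 0.89 in males (4 of 9 at least 2-fold higher, percentile 99.99) and 0.30 in females (percentile 94.1), with Esm1 at 3.35 and 1.56. Sinusoidal identity genes lay near 0 (−0.08 and 0.04, with 0 of 12 at 2-fold), and immediate early genes had 1.35 (percentile 100) and 0.06. Between the sexes, Cyp26b1, which degrades retinoic acid, was 7.29-fold higher in females in PBS and 3.56-fold in APAP, while Armcx4 (5.46-fold and 5.86-fold) and Rab3b (2.72-fold and 2.70-fold) were lower. Cluster 4 held most endothelial-like cells of each library except the female PBS one, where cluster 7 held 360 of 564. Alb was at 789, 1096, 2708 and 857 CPM of endothelial-like cells in the male PBS, male APAP, female PBS and female APAP libraries.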

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

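All tests weighed below were chosen after the result was seen, except the test for contractile cells of cluster 0. The differences between the sexes listed here were not tested, since each rests on 1 library per sex and treatment, and each is named because the median or ratio lay on opposite sides of 0 in the libraries compared.

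Cell cycle genes were higher in hepatocyte-like cells of the male APAP library, and the unnamed clusters 5 (8.05% of that library's cells) and 0 (6.25%), outside every named class, were larger there than in its PBS counterpart. RNA or cells of cluster 5 mixed into hepatocyte-like barcodes would bring Kupffer cell markers, whose summed CPM was 0.019 of what the mixed share would need, and cells of cluster 0 would bring contractile genes, which reached 0.036 of that need. Unequal depth is argued against by a median of 1.978 (at least 1.13 over members) after thinning, and a few barcodes as the whole cause by a median of 1.817 (at least 1.35) without the 3 leading barcodes of each library. A response of male hepatocytes to APAP stays open as a hypothesis, together with differences between animals, which 1 library per group cannot show.

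Pericentral genes were lower in hepatocyte-like cells of both APAP libraries. Fewer deep barcodes after APAP do not account for it, because in barcodes of at least 3000 UMIs the medians were −1.245 in males and −0.629 in females, below the random lists, and totals without mitochondrial and the most abundant genes left −1.482 and −0.913, which argues against a few genes taking the counts. A lower level of all zonal genes alike cannot be told apart in both sexes. The periportal median lay above the pericentral one by 1.549 in males, with intervals over members apart (−0.353 to 0.214 against −2.927 to −0.776), and by 0.517 in females, with intervals that overlap (−0.503 to 0.161 against −1.272 to −0.425). Loss of pericentral hepatocytes and lower expression within them both stay open and were not tested.

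Immediate early genes differed in direction between the sexes in hepatocyte-like cells, with a median log2 ratio of APAP over PBS of 1.617 in males and −0.329 in females (0.160 in cells of under 3000 UMIs), and of female over male of 0.88 in PBS and −1.339 in APAP. The stress-led cluster 3 does not account for the male value, which was 1.474 (at least 1.05 over members) without it. Stress at isolation shared by the whole male APAP suspension cannot be told apart, since Kupffer-like cells of that library gave −0.138 (−0.386 to 1.228) and endothelial-like cells 1.351. The day of isolation cannot be told apart either, because the labels give a day for 0 libraries. A difference between the sexes in the response to APAP stays open as well and was not tested.

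Further list medians also had opposite signs. Sinusoidal endothelial genes in hepatocyte-like cells had 0.567 in females and −1.08 in males after APAP, but the female value was −0.308 under the stricter filter and −0.028 with doublets kept, so the opposite sign was lost. Erythroid genes after APAP had −2.447 in females and 2.653 in males in hepatocyte-like cells, and −3.661 and 0.962 in Kupffer-like cells. Among hepatocyte-like cells of the female PBS library 1 cell held 61.6% of the 3529 erythroid UMIs. In the female APAP library 1 cell held 43.8% of 146. For female over male, erythroid genes had −1.513 in APAP and 3.712 in PBS in hepatocyte-like cells, and −1.336 and 4.684 in endothelial-like cells. Plasma protein genes in endothelial-like cells had −0.37 in APAP and 1.261 in PBS, but 0.123 in APAP with the highest doublet scores removed, so the opposite sign was lost there too. Interferon-stimulated genes in Kupffer-like cells had 0.627 in APAP and −0.662 in PBS.

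Single genes of hepatocyte-like cells with opposite signs after APAP were Igfbp1 (−3.244 in females and 2.252 in males), Egr1 (−2.627 and 1.515), Mt1 (1.495 and −1.555) and Cyp4a12a (4.205 and −2.621, with 1 and 5 UMIs in the female libraries). Of the male APAP UMIs of Igfbp1, 36.6% lay in 1 cell.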

How the results depend on the processing

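Cells of at least and of under 3000 UMIs, cells without cluster 3 or cluster 9, cluster 5 counted as Kupffer-like, barcodes of highest doublet scores removed, and cells without the 1 or 3 leading cells were alternatives chosen after seeing the data. No paired analysis was possible because each group had 1 library, so the groups share fewer than 2 replicate numbers, and no result came from a test. Pairing by sex or by treatment, which takes the sexes or treatments as replicates, was not chosen. A list median counts as kept when it stays within the interval over members, and a share ratio when it stays within its interval. A share ratio changes direction only where that interval excludes 1. A list median counts as changing sign only where the main median stood apart. Sign changes of other list medians are thus counted as kept or moved. Of the values for lists that answer a comparison, 169 were kept, 16 moved and 4 changed sign; of those for other lists 2601 were kept, 154 moved and 28 changed sign. Of the values for named genes 1509 stayed within their counting interval (or within 0.5 for a difference), 311 moved and 1 changed sign. These counts include the filters on low counts, which choose genes without changing a ratio, and each of them kept all 90 values. Among named genes 65 values moved and 21 stayed with thinned cells, and 59 moved and 28 stayed in cells of under 3000 UMIs. As means per cell 47 moved and 43 stayed. Most values thus moved under each of these alternatives, while most stayed under each of the others. Of the shares that answer a comparison 33 were kept, 8 moved and 1 changed direction, and of the others 77, 8 and 3. Share ratios that could not be formed under an alternative, such as the monocyte-like ones without a barcode filter, are not in these counts. Scaling moved the median of all genes for APAP over PBS by −0.132 in males and −0.229 in females with TMM, by −0.113 and −0.163 with size factors and by −0.147 in females (−0.129 for the difference of responses) with totals without the most abundant genes, and for female over male in PBS by 0.161 with TMM and 0.128 with size factors. Few cells were deep: 43 hepatocyte-like cells of the male APAP library held at least 3000 UMIs, against 227 in male PBS, 511 in female PBS and 106 in female APAP. The cause was not tested for any change below, all in log2 for hepatocyte-like cells unless another class is named.

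With cells thinned to 500 UMIs, female-biased genes for female over male had 4.224 in PBS and 2.130 in APAP, male-biased genes −4.497 in PBS, the pericentral difference of responses −0.150, APAP metabolism genes 0.076 after APAP in males and −0.260 for female over male in APAP, cell cycle genes after APAP 1.978 in males and 0.820 in females, and bile acid genes −0.368 for female over male in APAP and −0.752 for the difference. In cells of under 3000 UMIs the same lists had 4.863 and 2.481 for female-biased, −4.370 for male-biased (−0.065 for its difference), −0.045 for the pericentral difference, 0.019 and −0.635 for APAP metabolism, 0.459 for cell cycle in females, and −0.135 and −0.915 for bile acid genes, while after APAP periportal genes had 0.192 and immediate early genes 0.160 in females, and acute phase genes 0.070 in males. As means per cell, cell cycle genes had 2.016 in males and −0.433 in females, APAP metabolism −0.341 for female over male in APAP, acute phase 0.031 in males and the bile acid difference −0.971. The male cell cycle median was 4.342 with genes of at least 50 CPM, a filter that favours members high in male APAP. It was 3.287 in cells of at least 3000 UMIs and 1.817 without the 3 leading cells. The female one was 0.632 without the 1 leading cell, 0.613 without 3 and 0.823 under the stricter filter, and the periportal difference was 0.082 without 3 cells. Shares of cells with at least 2 cell cycle genes before thinning were 7.026%, 13.362%, 10.762% and 8.446% in male PBS, male APAP, female PBS and female APAP, and 0.197%, 2.371%, 0% and 0% with at least 3 genes after thinning.

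Under the stricter barcode filter the pericentral difference was −0.063, sinusoidal genes in hepatocyte-like cells had −0.308 after APAP in females and −0.448 for female over male in PBS (−0.247 in Kupffer-like cells), Kupffer-like Cxcl9 had −1.593 for female over male in PBS, and in endothelial-like cells bile acid genes had 0.027 after APAP in females and inflammatory cytokines 0.158 for female over male in PBS. With doublets kept, sinusoidal genes had −0.028 in female hepatocyte-like cells after APAP and −0.011 in Kupffer-like cells for female over male in PBS, where APAP metabolism genes had −0.070. With the highest doublet scores removed those Kupffer-like values were −0.055 and −0.177, and endothelial-like plasma protein genes had 0.123 for female over male in APAP and fatty acid oxidation genes 0.035 after APAP in females. Share ratios of APAP over PBS for Kupffer-like cells of males were 0.200 with the highest doublet scores removed, 0.502 without a filter, 0.708 at resolution 2.0, 0.734 with each library clustered on its own, 0.126 without cluster 9 and 0.701 with cluster 5. Hepatocyte-like ratios were 0.646 in males and 0.790 in females without a filter and 1.206 in females under the stricter one. The male stellate-like ratio of 0.834, whose interval includes 1, moved above 1, to 3.745 at resolution 0.5, 2.418 at resolution 2.0, 2.536 with the highest doublet scores removed, 1.898 under the stricter filter and 1.757 without a filter. In females the endothelial-like ratio was 0.501 with each library on its own, and the stellate-like ratio 0.336 under the stricter filter and 0.791 at resolution 0.5.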

Other observations

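No tests were run for the values in this part, which come from smaller classes and cover counting error only. Stellate- or fibroblast-like cells, which store vitamin A and make collagen, reached 50 cells in all but the male APAP library. The female APAP library fell below 50 such cells under alternatives. It held 48 with doublets kept, 41 with the highest doublet scores removed and 6 under the stricter filter. In females, collagen genes were lower after APAP in this class, with log2 ratios of −1.71 for Col1a1 (137 and 11 UMIs), −2.30 for Col1a2 and −1.40 for Col3a1, and −3.23 for fibronectin, Fn1. The stellate activation and matrix list had a median of −1.01 (percentile 0.300), with 5 of 9 members at least 2-fold lower and 1, Tagln at 1.36, higher. Macrophage transcripts in the same cells were also lower, with C1qc at 118 and 1 UMIs, Cd5l at 207 and 2 and Cxcl13 at 368 and 0 (at least 32.2-fold), and Clec4f was at 462 and 21.3 CPM. Gpx3, a secreted glutathione peroxidase, was 11.4-fold higher (3.51, 1.79 to 5.60) on 4 and 12 UMIs. The median of all genes in this contrast was −0.26, and the female APAP cells of the class summed to 93825 UMIs against 357245 after PBS. Between the sexes in PBS, Enpp2, the enzyme autotaxin, had 92 UMIs in females and 1 in males (6.61, 4.09 to 11.93), Nkain4 had 125 and 0, and Cd207, langerin, had 4 and 57 (13.4-fold lower in females).

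T-like and B-like cells could be compared between the sexes in PBS. The male PBS library held 48 B-like cells under the stricter filter, so that comparison was not recomputed there. In T-like cells the chemokine gene Ccl4 had 70 UMIs in 218 female cells and 1 in 58 male cells (log2 4.56, 2.03 to 9.88), Cblb, a brake on T cell activation, was 2.86-fold higher in females, and Dapl1 was 4.27-fold lower. In B-like cells the joining chain gene Jchain, expressed by antibody-secreting cells, had 1551 UMIs in 104 female cells and 0 in 54 male cells, at least 334-fold higher. The light chain gene Iglc3 was 23.0-fold higher (6125 and 172 UMIs), and Igha had 19 and 2 UMIs; immunoglobulin segments resemble each other, so their counts are uncertain. Alb was at 1479 CPM in female and 218 CPM in male T-like cells, and at 1793 and 329 CPM in B-like cells. Cluster 5 held Kupffer cell transcripts beside its proliferation genes, with Clec4f at 1249, 1328, 1175 and 1374 CPM in male PBS, male APAP, female PBS and female APAP. Cluster 0 cells had a median of 801 UMIs.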
